A study of Homo sapiens with 6 samples.

How the data were processed

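Cardiomyocytes derived from the H9 human embryonic stem cell line were profiled as 3 wild-type and 3 ADPRHL1 knockout samples. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected with oligo-dT, fragmented and copied with random primers, and libraries were amplified by PCR. No source used here says whether libraries kept strand. The genome build hg38 is named in the submitters' processing notes without a role. The aligner, the counting tool and the annotation are not given in the sources used here.

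The authors deposited 1 table of 28092 genes with, for each sample, an estimated read count and an expression value, and the mean count of each group. The deposited read counts were taken as estimated counts, which need not be whole. The headers name them only as read counts, but just 11.9 to 13.0% of the values above 0 in a sample were whole numbers. The deposited expression values were read as FPKM, although the header names no unit, because the length implied by count, sample total and value varied by under 2% between samples for 41.2% of 11511 well-covered genes, with a median implied length of 3471 bases. The deposited group means matched the means of their samples within 0.0003 and were not used further. Such estimates divide reads between genes, so genes with near-identical copies, overlapping genes and antisense genes are less certain than their p-values say.

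Of the rows, 24137 had an Entrez gene ID, of which 23433 matched a RefSeq symbol and 704 did not. Symbols were taken by ID, since 27 had been turned into calendar dates in the table. The other 3955 rows were unnamed gene models. The largest row was one of them and took 12.8 ± 0.316% of counts in wild type and 11.4 ± 0.220% in knockout (SD, n = 3). All unnamed models together took 14.6 ± 0.326% and 13.2 ± 0.233%. They stayed in the fit, and leaving them out was tried as an alternative. Coordinates are those of RefSeq on GRCh38 (hg38), and transcript lengths those of GENCODE.

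Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM, fitted with robust quasi-likelihood dispersions and tested for genotype alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count of genes changed by 2-fold or more was taken among those calls. Standard errors of log2 fold changes were derived from the F statistic and are approximate. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 33 lists, of which 12 of 22 lists by function and 4 of 11 marker lists passed. With an estimated correlation 7 lists passed in all. Depth was 21179650 to 21405718 counts per sample, so 3 counts stand for about 0.140 CPM, and the common biological coefficient of variation was 0.0791. Pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 3.37 to 6.81). All 6 samples were counted separately, although this difference does not show that they came from separate cultures.

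The samples, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. The rule named ADPRHL1 first. It then named the 8 largest rises and 8 largest falls by fold among called genes with non-overlapping groups, an informative symbol and a mean of at least 1 CPM. In each list it named the 2 risers and 2 fallers of smallest p, and whatever their values it named ROCK1, ROCK2, ITGB1, VCL, PXN, PTK2 and TNNT2, with 1 further gene. The lists by function that are described were focal adhesion and integrins, SRF and MRTF targets, YAP and TEAD targets, sarcomere, calcium handling and ion channels, intercalated disc, extracellular matrix, cardiac transcription factors, ventricular and atrial chamber, hypertrophy and stress, cell cycle, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, sterol synthesis, unfolded protein and integrated stress response, p53 targets, interferon and inflammation, ADP-ribosylation, and developmental signalling. Results of 1 further list and of some genes are not reported here, although counts over all genes and lists include them. Marker lists covered cardiomyocytes, fibroblasts, smooth muscle, endothelium, epicardium, endoderm, neural, neural crest, pluripotent, skeletal muscle, haematopoietic and epithelial cells.

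Alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter on mean CPM, a test against a fold of 1.5, the replicate number as a block, each replicate left out in turn, camera with an estimated correlation, and fry. Unrounded counts, named genes only and limma on log2(FPKM + 1), for genes with FPKM of at least 1 in 3 samples, were added after the data were seen. The gene test was tested on simulated counts with known changes for 18564 genes. It recovered 21 of 50 genes changed by 1.3-fold, 34 of 50 by 1.5-fold, 39 of 50 by 2-fold and 49 of 50 by 4-fold, with 10 false among 153 calls. The smallest simulated fold was changed after earlier runs of this test had been seen, to keep its value apart from measured ones, and a larger fold is recovered more often. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.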

Results

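Polyadenylated RNA was sequenced from cardiomyocytes derived from H9, an established human embryonic stem cell line, as 3 wild-type and 3 ADPRHL1 knockout samples collected within 3 days of re-seeding. ADPRHL1 encodes a heart-enriched member of the ADP-ribosylhydrolase family that is regarded as a pseudoenzyme. The study asked how loss of ADPRHL1 affects focal adhesions, the integrin-based contacts between cells and matrix, and its title links the gene to signalling through ROCK, a kinase that drives actomyosin contraction. Estimated counts summed to between 21179650 and 21405718 per sample, so depth was close to equal across all samples. Changes are given as log2 fold changes, knockout minus wild type, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels as TMM-scaled CPM (counts scaled to library size; mean ± SD, n = 3 per group). Genes named within a list, unless fixed by name, were picked by smallest p and need not have its largest folds. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

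The targeted gene was checked first. ADPRHL1 (Entrez 113622; hg38, chromosome 13, 113399610 to 113453488) stood at 83.7, 79.6 and 79.4 CPM in the wild-type samples and at 6.40, 5.81 and 7.57 CPM in the knockout samples. It averaged 80.9 ± 2.41 CPM in wild type and 6.59 ± 0.893 CPM in knockout, a log2 fold change of -3.62 (SE 0.0818, adjusted p = 6.75e-12), so every library had the ADPRHL1 level its label gives. The fall was 12.1-fold in estimated counts and 26.6-fold in FPKM, as the gene length implied by the deposited values went from 2045 ± 8.98 bases to 4645 ± 923 bases.

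Most contractile and calcium-handling genes tested were lower in the knockout samples and most fibroblast and endothelial markers were higher, while matrix genes moved both ways, 48 of 83 up and 28 down. MYH7, the beta myosin heavy chain, averaged 262 ± 2.91 CPM in wild type and 42.0 ± 0.739 CPM in knockout, and the Z-disc gene LDB3 averaged 444 ± 4.65 CPM in wild type and 71.4 ± 0.999 CPM in knockout. ACAN, the large proteoglycan of cartilage, rose from 23.1 ± 1.27 CPM to 226 ± 17.1 CPM, and SOX17, a transcription factor of endothelium and endoderm, from 3.96 ± 0.125 CPM to 35.1 ± 1.83 CPM. Of 19558 genes tested, 11151 changed at an adjusted p under 0.05, with 5553 higher and 5598 lower in knockout. By 2-fold or more, 1982 genes were higher and 1178 were lower. The knockout and wild-type values did not overlap for 64.4% of the genes tested, where chance gives 10%.

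**Figure D1:**
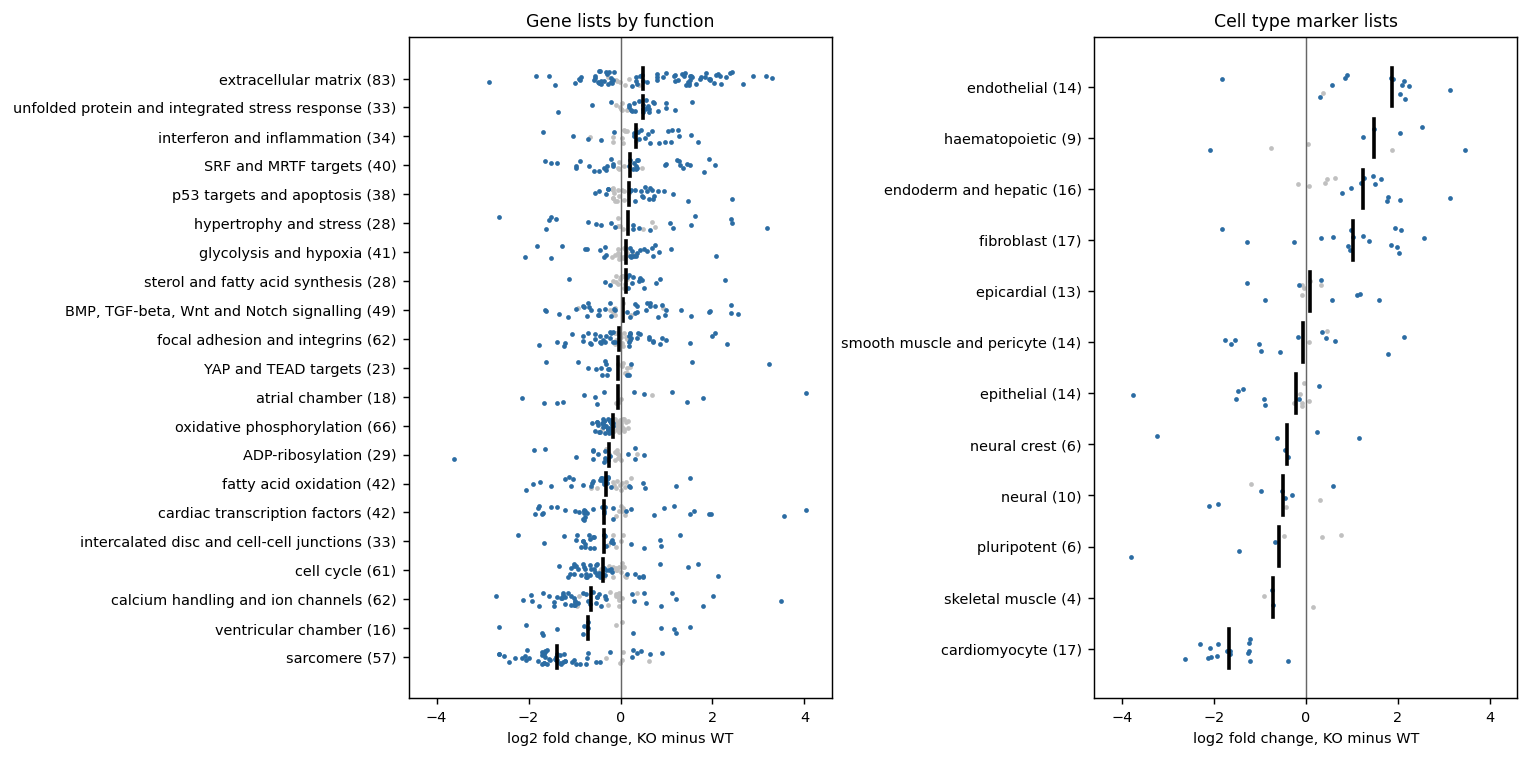
Log2 fold change (horizontal axis, knockout minus wild type) of each tested member of the gene lists described here, fixed before the data were examined, with lists by function on the left, cell type markers on the right and the number of tested members in parentheses. Blue points passed an adjusted p of 0.05, grey points did not, vertical position within a list is random, and black bars mark medians, which run from -1.38 for sarcomere genes and -1.67 for cardiomyocyte markers up to 1.87 for endothelial markers.

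Genes of focal adhesions moved in both directions. The integrin genes ITGA5, the alpha subunit of the main fibronectin receptor, and ITGA8 rose, ITGA5 at 109.7 ± 2.84 CPM in wild type and 454 ± 54.9 CPM in knockout (log2 fold change 2.05, SE 0.0800) and ITGA8 at 13.6 ± 1.15 CPM in wild type and 54.2 ± 3.26 CPM in knockout (1.99, SE 0.0771). The adaptor gene SORBS2 (-1.76, SE 0.0557) and TLN2, a talin gene expressed in muscle (-1.39, SE 0.0509), fell. Of 62 focal adhesion genes tested, 21 rose, 24 fell and 17 did not pass, or 22 and 24 adjusted over the list alone. The list did not stand apart from other genes (camera adjusted p = 0.684), with a median of -0.027, a mean of 0.015 and a test pointing down. Under fry, which does not compare a list with other genes, it passed (adjusted p = 0.0340). The fixed members changed by little: VCL, which encodes vinculin, averaged 826 ± 14.3 CPM in wild type and 742 ± 26.3 CPM in knockout (-0.16, adjusted p = 0.0130), PXN, which encodes paxillin, fell by 0.15 (adjusted p = 0.0155) and PTK2, which encodes focal adhesion kinase, rose by 0.18 (adjusted p = 0.00903). ITGB1, the common integrin beta subunit, averaged 292 ± 24.9 CPM in wild type and 269 ± 26.1 CPM in knockout, a difference of -0.12 that did not pass (adjusted p = 0.237). The PXN call ended without knockout replicate 1 (adjusted p = 0.0512) or wild-type replicate 2 (0.0717) and on FPKM (0.101), the PTK2 call ended without wild-type replicate 1 (0.0746), and ITGB1 passed without knockout replicate 1 (-0.20, adjusted p = 0.0276).

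The kinase genes ROCK1 and ROCK2 gave different results. ROCK1 fell from 100.1 ± 4.68 CPM to 75.9 ± 6.06 CPM (log2 fold change -0.40, SE 0.0628, adjusted p = 1.63e-04). ROCK2 averaged 93.4 ± 11.8 CPM in wild type and 94.1 ± 4.36 CPM in knockout, a difference of 0.011 that did not pass (adjusted p = 0.926). All 17 cardiomyocyte markers fell and 14 of 17 fibroblast markers rose in the same samples as these focal adhesion and kinase gene changes (medians -1.67 and 1.04). RNA levels do not measure ROCK activity, which was not analysed here.

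**Figure D2:**
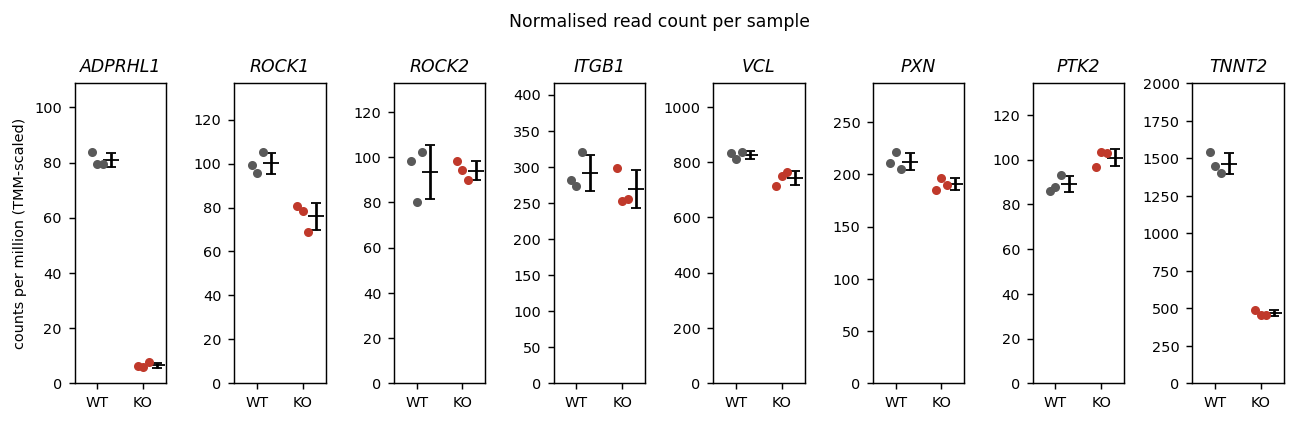
Normalised read count (vertical axes, TMM-scaled CPM, each starting at 0) of the targeted gene and of 7 genes named in advance, in the 3 wild-type (grey) and 3 knockout (red) samples. Black marks give the mean ± SD of each group; ADPRHL1 averaged 80.9 CPM in wild type and 6.59 CPM in knockout, while ROCK2 averaged 93.4 and 94.1 CPM.

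Targets of the actin-responsive factors SRF and MRTF, and of YAP and TEAD, were also mixed. IER2 (1.45) and EGR1 (0.99) rose, while FHL1 (-1.51) and SYNPO2 (-1.38) fell. Among 40 SRF and MRTF targets 20 rose and 15 fell (21 and 15 adjusted over the list alone; median 0.20, camera adjusted p = 0.535). Among 23 YAP and TEAD targets 5 rose, including NT5E (3.22) and IGFBP3 (1.56), and 11 fell, including TGFB2 (-1.61) and AMOTL2 (-0.71) (median -0.048, camera adjusted p = 0.836). Cardiomyocyte markers (median -1.67) fell beside both lists.

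Sarcomere genes fell almost throughout. Of 57 tested, 46 fell and 6 rose, with a median of -1.38 (camera adjusted p = 1.01e-67). TNNT2, the cardiac troponin T gene, averaged 1463 ± 70.3 CPM in wild type and 467 ± 20.3 CPM in knockout (-1.65, SE 0.0542, adjusted p = 1.23e-10), and MYH7 (-2.64) and LDB3 (-2.63) fell further. The intermediate filament gene DES (0.45) and the filamin gene FLNC (0.35) rose. Calcium handling and ion channel genes fell as well, 37 of 62 against 10 that rose (11 rose adjusted over the list alone; median -0.63, camera adjusted p = 4.55e-11). SLC8A1, the sodium-calcium exchanger gene, averaged 683 ± 22.3 CPM in wild type and 156 ± 7.96 CPM in knockout, and RYR2, the calcium release channel gene of the sarcoplasmic reticulum, averaged 174 ± 3.20 CPM in wild type and 45.3 ± 3.36 CPM in knockout, while S100A1 (3.50) and KCNK3 (2.02) rose. Of 33 intercalated disc and junction genes 23 fell, including CTNNA3 (-2.23) and PKP2 (-1.66), and 5 rose, including CDH11 (1.29) and GJA1 (0.89) (median -0.37, camera adjusted p = 8.64e-08). These 3 calls held with an estimated correlation (adjusted p = 0.0305, 0.0305 and 0.0485). All 17 cardiomyocyte markers, 12 of them also sarcomere genes, fell alongside these groups (median -1.67).

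Cardiac transcription factor genes fell more often than they rose. Of 42 tested, 25 fell, including CASZ1 (-1.72) and TBX20 (-1.69), and 11 rose, including FOXC1 (1.92) and NR2F1 (4.04) (median -0.35, camera adjusted p = 5.99e-05; adjusted p = 0.0541 with an estimated correlation). Ventricular genes fell as a list (9 of 16, 5 rose; median -0.71, camera adjusted p = 4.41e-07; adjusted p = 0.0380 with an estimated correlation), with MYH7 (-2.64) and MYL3 (-2.06) lower and GJA1 (0.89) and IRX5 (1.52) higher. That call ended under limma-voom (adjusted p = 0.0606) and on FPKM (0.152). In the atrial list 8 of 18 fell, including MYH6 (-2.14) and MYL7 (-1.67), and 6 rose, including NR2F1 (4.04) and SLN (1.12); its median was -0.062, its mean 0.065 and its test pointed down (camera adjusted p = 9.88e-04; adjusted p = 0.0652 with an estimated correlation). The atrial call ended under limma-voom (adjusted p = 0.272) and on FPKM (0.292) too. Hypertrophy and stress genes split, with 11 of 28 higher, including LIF (3.19), and 10 lower, including MYH7 (-2.64) and FHL1 (-1.51) (12 and 10 adjusted over the list alone). The median of that list was 0.17 and its mean 0.22, while its test pointed down without passing (camera adjusted p = 0.700). The 17 cardiomyocyte markers fell beside these lists too, with a median of -1.67.

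Extracellular matrix genes rose more often than they fell. Of 83 tested, 48 rose and 28 fell (median 0.48, camera adjusted p = 3.25e-15; adjusted p = 0.220 with an estimated correlation). The risers of smallest p were the cartilage genes ACAN (3.29) and COL11A1 (2.89), and the fallers of smallest p were SPON1 (-2.86) and EMILIN2 (-1.42). Markers of fibroblasts rose beside them, 14 of 17 (median 1.04). Genes of BMP, TGF-beta, Wnt and Notch signalling moved both ways, 22 of 49 up and 19 down (22 and 21 adjusted over the list alone; median 0.062, camera adjusted p = 0.190; adjusted p = 0.0134 under fry), with TCF7 (1.94) higher and TGFB2 (-1.61) and BMP7 (-1.64) lower.

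Many genes of mitochondrial energy metabolism were lower. In fatty acid oxidation 24 of 42 genes fell, including ACACB (-1.51) and PPARGC1A (-1.21), and 6 rose, including the lipid droplet gene PLIN2 (1.20) and PPARD (0.53) (median -0.32, camera adjusted p = 0.0120; adjusted p = 0.356 with an estimated correlation). ACACB makes malonyl-CoA, an inhibitor of fatty acid uptake into mitochondria. In oxidative phosphorylation 33 of 66 genes fell, including UQCRC2 (-0.51) and NDUFA5 (-0.55), and 0 rose (median -0.16, camera adjusted p = 0.0209; adjusted p = 0.727 with an estimated correlation). The oxidative phosphorylation call ended without knockout replicate 2 (adjusted p = 0.0736). Cardiomyocyte markers, from a mitochondria-rich cell type, fell beside both lists (median -1.67). Glycolysis and hypoxia genes did not move as a list (17 of 41 rose, 10 fell, 18 and 10 adjusted over the list alone; median 0.12, camera adjusted p = 0.891), with VEGFA (0.76) and CA12 (2.07) higher and PDK1 (-2.07) and ENO3 (-1.27) lower. Sterol and fatty acid synthesis genes did not pass either (13 of 28 rose, 3 fell; median 0.11, camera adjusted p = 0.0731), with ACLY (0.78) and INSIG1 (0.85) higher and STARD4 (-1.13) and LSS (-0.34) lower, but passed with upper-quartile factors (adjusted p = 0.0475), under limma-voom (0.0486), without knockout replicate 3 (0.0348) and under fry (0.00385).

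Many stress-response genes were higher. In the unfolded protein and integrated stress response 24 of 33 genes rose, including the paired cystine transporter genes SLC7A11 (1.19) and SLC3A2 (0.99), and 3 fell, including VLDLR (-1.36) and PHGDH (-0.61) (median 0.48, camera adjusted p = 4.71e-04; adjusted p = 0.263 with an estimated correlation). Of 38 p53 target and apoptosis genes 19 rose, including the cell cycle inhibitor gene CDKN1A (1.48) and GDF15 (2.42), and 5 fell, including TP53I3 (-0.57) and CCNG1 (-0.28) (median 0.19, camera adjusted p = 0.0133; adjusted p = 0.105 with an estimated correlation). In the cell cycle list 35 of 61 genes fell, including ANLN (-1.33) and MKI67 (-1.10), and 9 rose, including CCND1 (2.12) and CDKN1A (1.48) (36 fell adjusted over the list alone), but the list did not pass in the main test (median -0.37, camera adjusted p = 0.110), although it did under limma-voom (adjusted p = 0.00169), with no low-count filter (0.0256), on FPKM (0.00618) and under fry (0.00396). Interferon and inflammation genes did not pass as a list (18 of 34 rose, 5 fell, 19 and 5 adjusted over the list alone; median 0.34, camera adjusted p = 0.226), with ICAM1 (1.53) and NFKBIA (0.65) higher and VCAM1 (-1.68) lower, but passed under limma-voom (adjusted p = 0.0265) and fry (0.0218). Of 29 ADP-ribosylation genes 13 fell and 4 rose (median -0.26, camera adjusted p = 0.0133, or 0.461 with an estimated correlation). That list holds the targeted gene ADPRHL1, its lowest member at -3.62, and was not tested without it. MACROH2A1 (-0.60) was also among the fallers, and ADPRS (0.50) and SIRT6 (0.32) were among the risers. The call of the list ended on FPKM (median -0.11, adjusted p = 0.0822), and that of SIRT6 without wild-type replicate 1 (adjusted p = 0.0517), wild-type replicate 3 (0.0652) or knockout replicate 3 (0.0557). Cardiomyocyte markers fell and fibroblast markers rose beside all of these lists (medians -1.67 and 1.04).

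Markers of other cell types differed between the groups. Besides the 17 cardiomyocyte markers that fell, including MYH7 (-2.64) and MYBPC3 (-2.29) (camera adjusted p = 1.26e-65; adjusted p = 0.0305 with an estimated correlation), 14 of 17 fibroblast markers rose, including PRRX1 (1.99) and DCN (1.94), and 3 fell, including POSTN (-1.83) and TCF21 (-1.27) (camera adjusted p = 7.07e-11; adjusted p = 0.0485 with an estimated correlation). Endothelial markers rose, 12 of 14 (13 adjusted over the list alone; median 1.87), including SOX17 (3.15) and FLT1 (1.89), with EMCN (-1.83) lower (camera adjusted p = 3.48e-06; adjusted p = 0.0419 with an estimated correlation; median 0.998 on FPKM). Endoderm and hepatic markers rose, 11 of 16 with 0 lower (median 1.24), including SOX17 (3.15) and HNF4A (1.78) (camera adjusted p = 0.00211; adjusted p = 0.533 with an estimated correlation). The remaining lists did not pass in the main test, while under fry every tested marker list did (largest adjusted p = 0.0340). Smooth muscle and pericyte markers split, 5 of 14 up and 7 down (6 and 7 adjusted over the list alone; median -0.049, camera adjusted p = 0.207), with CSPG4 (1.80) and PDGFRB (2.14) higher and MYOCD (-1.76) and LMOD1 (-1.64) lower. Epicardial markers also split, 5 of 13 up, including TBX18 (1.60) and BNC2 (1.10), and 3 down, including TCF21 (-1.27) and the gene WT1 (-0.88) (median 0.10, camera adjusted p = 0.466). Of 14 epithelial markers 7 fell, including KRT5 (-3.76) and GRHL2 (-1.48), and EPCAM (0.29) rose (median -0.21, camera adjusted p = 0.0733). The epithelial list passed under limma-voom (adjusted p = 0.0299), with no low-count filter (0.0210), with the replicate block (0.0315), without wild-type replicate 1 (0.0318), without knockout replicate 3 (median -0.40, adjusted p = 0.0230) and under fry (0.00850). Neural markers gave 6 fallers of 10, including DCX (-2.09) and NES (-0.29), and the riser TUBB3 (0.59) (median -0.49, camera adjusted p = 0.237). Neural crest markers gave 4 fallers of 6, including TFAP2A (-3.23) and ERBB3 (-0.62), and the risers SNAI2 (1.17) and ETS1 (0.25) (median -0.41, camera adjusted p = 0.700), although ERBB3 stood at -0.0098 on FPKM (adjusted p = 0.938). Of 6 pluripotency markers 3 fell, including L1TD1 (-3.81) and LIN28B (-1.45) (median -0.58, camera adjusted p = 0.299), and of 9 haematopoietic markers 5 rose, including RUNX1 (1.25) and LYZ (1.48), with SPI1 (-2.08) lower (median 1.48, camera adjusted p = 0.239). With 4 skeletal muscle markers tested, too few for the list test, CKM (-0.71) and TNNT3 (-0.73) fell, although TNNT3 stood at 0.022 on FPKM (adjusted p = 0.898). For every list described here whose counts adjusted over the list alone are not given, they equalled those over all genes.

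Most of the largest rises by fold were of genes with few counts in wild type. CYGB, which encodes cytoglobin, had 7 counts over the wild-type samples and 622 over the knockout samples, a ratio of 87.7 (95% exact counting interval 42.3 to 219). NKX6-2 had 3 and 190 counts, a ratio of 62.5 (21.1 to 306). ENPP1, an enzyme that makes pyrophosphate outside the cell, rose from a measurable level, 8.57 ± 1.05 CPM in wild type and 196 ± 11.7 CPM in knockout (4.51, SE 0.0812). FGFBP2 (5.36), FAM180A (4.98), HIC1 (4.67) and NPPC (4.35) completed the named protein-coding risers. The antisense gene EFCAB14-AS1 (5.60, adjusted p = 0.0104) is uncertain, since no source used here says that counting used strand. Its call ended in a fit with the replicate number as a block (adjusted p = 0.0552). All of its 14 wild-type counts lay in replicate 3, and its knockout counts ran from 130 to 376. Among the largest falls, KRT1, an epidermal keratin gene, had 158 counts in wild type and 0 in knockout, at least 17.7-fold lower against a floor of 3 counts per library. GABRP averaged 52.3 ± 5.25 CPM in wild type and 0.310 ± 0.115 CPM in knockout. SERPINB13 had 142 and 4 counts, a ratio of wild type to knockout of 36.0 (13.7 to 134), and FRMD7 had 437 and 5, a ratio of 88.5 (37.6 to 274). MUC16 (-6.16), VTCN1 (-4.77) and MAGEA4 (-4.56) also fell, as did the antisense gene RBM5-AS1 (-5.60), which is uncertain for the same reason. Intervals and floors cover counting error only. Epithelial markers, with 7 of 14 lower, moved beside these falls.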

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

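The comparison of implied lengths in this part was chosen after the values were seen. The implied length of ADPRHL1 in the knockout samples, 4645 ± 923 bases against 2045 ± 8.98 bases in wild type (SD, n = 3), was singled out because it is a signal outside the count comparison. The ratio was 2.24 (limma adjusted p = 0.0258, over 11783 genes). It ranked at percentile 99.8 among 1735 genes with a knockout mean of 80 to 250 counts. Those genes were not matched for the span of their transcript lengths, and genes under FPKM 1 in any sample were left out. The rank therefore does not decide whether chance at the low counts left in knockout gave the ratio. Transcripts of ADPRHL1 in GENCODE span 839, 1341, 1877 and 9759 bases, and a candidate explanation is that the remaining reads lie more on the longest one, which values per gene do not test. How the cells were edited was not analysed here, so a biological explanation was not tested.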

How the results depend on the processing

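Alternatives chosen after seeing the data were the FPKM test, unrounded counts and leaving out unnamed models. The count of changed genes (11151) stayed within 1.5 times under every alternative but 1, ranging from 8265 on FPKM to 11510 without a filter. Tested against a fold of 1.5, which by construction calls fewer genes, 3257 changed, 1872 higher and 1385 lower. On FPKM 579 genes were higher and 458 lower by 2-fold or more, of 14219 tested. Adding 1 before the log shrinks folds of low values by construction, and how far this lowered the counts was not tested. In both tests 35 genes changed, in opposite directions. Also on FPKM, TNNT3 turned to 0.022 (adjusted p = 0.898), and the cause was not tested. With each replicate left out, changed genes ranged from 10062 to 10597, higher from 4978 to 5240, lower from 5084 to 5416, higher by 2-fold from 1832 to 2179 and lower by 2-fold from 1152 to 1257. Lists by function ranged from 11 to 13, marker lists from 4 to 5 and the focal adhesion median from -0.058 to -0.035. With an estimated correlation 4 lists by function passed. Under fry, which asks whether genes of a list move on balance and does not compare them with other genes, 11 marker lists passed, as did focal adhesion (median -0.027, adjusted p = 0.0340). With the replicate number as a block 10702 genes changed, 10484 of them among the 11151. Same-numbered samples did not deviate together (correlations 0.0225, -0.00806 and -0.0135), and not every sample matched its own number best. The values thus show no pairing by number. With 3 samples per group this cannot show whether same-numbered samples were handled together, which the labels do not state. Over all settings, those above included, values of named genes kept side and direction in 2261 cases, lost the call in 34, gained it in 1 and turned in 1; lists other than focal adhesion kept theirs in 518, gained a call in 23 and lost it in 15. DESeq2 and the 1.5-fold test gave no list values, and pseudocounts and filters for normalized values did not apply to the count test. In the simulation small changes were missed most often, with 21 of 50 1.3-fold changes recovered. Few genes were changed there, while 57.0% of tested genes were called in the data. The adjusted threshold was therefore stricter in the simulation, which does not give the share of small changes missed in the data.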

Other observations

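Tests chosen after values were seen were the spread of cardiomyocyte markers, the scaling check, the camera test of 15 cartilage and bone genes, the comparison of endothelial with epithelial markers and the chromosome test, which was also narrowed to whole chromosomes then. The cartilage and sinoatrial lists were prompted by genes already seen, and FN1 in the second endoderm list had been seen. The squamous and amnion list and the other second lists were not among the lists fixed in advance either.

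Genes of cartilage and bone were higher in the knockout samples. Of 26 tested, 23 rose and 2 fell, with a median log2 fold change of 1.87. COL2A1, the main collagen of cartilage (1.73), COL9A2 (2.66), COL11A2 (2.65) and RUNX2, a transcription factor of bone (1.88), were among them, while PTH1R (-0.73) and DLX5 (-1.31) fell. These genes were named after their values were seen. Leaving out the genes that prompted the list and those of the lists fixed in advance, 12 of 15 rose and 2 fell (median 1.52, camera p = 8.54e-10; p = 0.00461 with an estimated correlation). Fibroblast genes outside the first list rose in 12 of 20 cases and fell in 3 (median 0.81, camera adjusted p = 6.97e-06; adjusted p = 0.200 with an estimated correlation). Sinoatrial and atrioventricular genes did not move as a list, with 8 of 20 higher, SHOX2 among them (3.56), and 10 lower, ISL1 among them (-1.86; median -0.10, camera adjusted p = 0.950).

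Cardiomyocyte and sarcomere genes were lower in knockout, and technical and biological explanations were weighed. Scaling or depth moves every gene alike and is argued against, since the median of the 17 cardiomyocyte markers differed by -1.67 from that of all other genes, with each of them lower by over 3 standard errors. A bias with GC content, length or level is argued against too, since the sarcomere median was -1.38 before and -1.40 after regression on them (R squared 4.22%, 16394 genes). A lower share of cardiomyocytes would lower all markers alike only if other cells lacked them and all cardiomyocytes expressed them equally, which was not tested. Their log2 fold changes ran from -0.39 for NKX2-5 to -2.64 for MYH7, with an SD 9.29 times their median standard error. This spread therefore cannot decide whether a lower share was the whole cause. A lower share may account for part or all of the fall, and lower expression per cell or a less mature state in knockout may contribute. Bulk RNA does not separate these.

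Markers of other cell types moved apart. Of 14 endothelial markers 12 rose, while of 14 epithelial markers 7 fell, 1 rose and 6 did not pass (medians 2.08 apart). An equal gain of all other cells is argued against only if marker RNA follows cell number, which was not tested. Fewer squamous or amnion-like epithelial cells may contribute. In a second list without the genes named above 22 of 30 fell and 4 rose (median -1.02, camera adjusted p = 6.48e-05, or 0.200 with an estimated correlation). KRT17, its most abundant keratin, fell from 85.8 to 23.4 CPM, while the 4 risers were KRT4 (2.62), S100A2 (2.54), PKP1 (1.08) and TP63 (0.45). Genes expressed together fall together in the same samples, so this list is no separate test of the falls named above. For more endothelial cells the second list had a median of 0.43, with 12 of 21 higher and 2 lower. For more endoderm or hepatic cells the second list had a median of 0.38, with 10 of 22 higher and 4 lower. Both medians lie between the bounds set for the tests, so they decide neither gain. Endothelial marker RNA still rose more often than it fell in both lists. In the second, CD93 (3.12) and PLVAP (3.31) were among the risers, and PROX1 (-1.798) and EPAS1 (-0.47) fell. That list did not pass (camera adjusted p = 0.0979). Whether more endothelial cells or higher expression per cell gave these rises was not tested. An effect of the genotype on differentiation and a difference between cell batches or clones stay open, untested.

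A whole chromosome gained or lost in knockout was tested as a hypothesis. The largest difference of a chromosome's median from that of all other genes was -0.14, on chromosome 13, which argues against a gain or loss of a whole chromosome in all cells, while parts of chromosomes and subsets of cells were not tested. The window of 40 expressed genes with the largest median, chosen after its values were seen, lay on chromosome 4 from 112297369 to 128875224 (hg38) with a median of -0.50, and of -0.27 after regression on GC content, length and level.

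The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 11151 genes in edgeR and the highest other 0 (12024 and 165 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For lists by function the real split gave 12 and the highest other 9, and 1 of 10 gave as many. For marker lists the real split gave 4 and the highest other 5, and 7 of 10 gave as many. Camera at the preset correlation called lists in splits where edgeR called no gene. Every other split mixed both genotypes on each side, so the genotype difference widened the spread within groups and partly remained between them. The other splits are thus no null, and neither their 0 genes nor their called lists measure false calls.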
